A study of Schizosaccharomyces pombe with 24 samples.

How the data were processed

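Total RNA from fission yeast (Schizosaccharomyces pombe) was measured on 24 two-colour Agilent arrays of a custom design. Per the labels' protocols, cells were harvested on ice, total RNA was prepared with the RiboPure-Yeast kit, and labelling used either the Quick Amp or the Low Input Quick Amp kit. Which of the kits was used for which array is not given. Each sample was labelled with Cy3 and hybridised against Cy5-labelled RNA of the wild-type strain F108 growing exponentially in rich medium (YES), per the labels, with no dye swap. The common reference cancels in comparisons between arrays, whereas a dye effect that depends on signal strength does not.

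The scanner files were made with Agilent Feature Extraction 9.5.3.1, per the file headers. They hold mean and local background intensity in both channels, and the processed signals, also an intensity, which the authors' scanner software had background-subtracted and dye-normalized, per the file headers. They also hold a log10 ratio of red over green, per the file headers, which is reference over sample here. The deposited series matrix holds log2 ratios of sample over reference. Its values differed from the sign-turned scanner ratio by at most 0.00497 to 0.0321 per array, its column medians lay between -0.0551 and 0.0189, and no centring of genes was found. How the small differences arose is not stated.

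Starting from the mean and background intensities, the background was corrected with normexp (offset 50) and each array was normalized by loess in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table), with control spots and outlier spots at weight 0. Spots that the scanner software marked as non-uniform or as population outliers were left out, and saturated spots were kept. The array carries 10118 spots for 5059 genes, with 2 probes per gene, and 536 control spots. A gene's value was the mean of its probes. The standard deviation of the difference between a gene's probes was 0.181 to 0.339 on the log2 scale, and their correlation 0.804 to 0.952, per array. Of the genes, 5022 matched a locus tag of the assembly ASM294v3 and 4201 had a symbol of their own, and the others keep the systematic name. Positions of the probes within genes were not available, so no coordinates are given. Signals of near-identical copies (tlh1 and tlh2, other subtelomeric families, Tf2 elements, histone genes and ribosomal protein paralogues) may be shared between their probes, and values of these genes are uncertain in that respect.

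A gene was tested where it was well above background in either channel on at least 25% of the arrays of the fit and had values in at least 3 matched pairs, where the design holds that many. The 18 germination arrays were fitted together in limma with additive terms for harvest (6, 8, 10 and 12 h, and 10 h with hydroxyurea) and genotype. The 6 temperature arrays were fitted with a term for each of the 4 groups of strain and temperature. Empirical Bayes moderation used a trend on intensity, and every adjusted p is limma's after Benjamini-Hochberg adjustment over the genes tested in a comparison, with 0.05 as the threshold. Each genotype was measured on 1 array per harvest, so the tests measure how steady a difference was over harvests, and a steady technical difference between arrays would pass them too. All log2 differences are the first-named group minus the second. Where a gene was not well above background on any array of a group, only a bound is given, as "at least N-fold". It compares the mean of the brighter group with the lowest signal well above background in the other (per-channel values after loess and Aquantile normalization, open to dye bias).

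In all, 12 gene lists were written by hand from textbook knowledge: M phase and cytokinesis, cell separation, MBF (genes of the G1/S transition), histones, core stress response, heat shock chaperones, mating and early meiosis, spore wall and sporulation, ribosome biogenesis, ribosomal proteins, amino acid and pyrimidine synthesis, and iron uptake (Fep1 targets). Each was tested in each of 10 comparisons with limma's camera (preset correlation 0.01) and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Of the 120 list tests, 49 passed with the preset correlation and 4 with an estimated one. The latter test used the residual degrees of freedom of each fit, 10 for germination and 2 for temperature, so it had little power in the temperature fit. For single arrays, a list's median was set against 10000 random lists of the same size matched on mean expression.

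Genes were named by rule. Named are the targeted genes sak1, fkh2 and sep1, and the marker ura4. Added are up to 8 genes with the largest increase and up to 8 with the largest decrease among those past the threshold with the same sign in every matched pair without hydroxyurea (at both 2 h and 4 h for the 36 °C comparisons). Also named are up to 4 members of each list, ranked by the moderated statistic whether or not they passed. A gene was left out where naming it added nothing, and 2 genes within the rule are not reported here. The groups, tests, lists, naming rule and most alternatives were fixed before the data were examined.

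The arrays came from 4 slides and 2 scan sessions. Slide 4, scanned in a session of its own, held all 4 arrays labelled sak1Δ of the germination series and 2 of the wild-type temperature arrays. Values were computed with slide as a fixed or random block, and within slides 1 and 2, where the design allowed it. Other alternatives were the scanner's log ratios, the series matrix, other background corrections, scalings and probe filters, the brightest probe per gene, robust or trend-free moderation, blocking by replicate, fitting only the groups compared, leaving out hydroxyurea arrays, and leaving out each array in turn. Alternatives added after seeing the data were keeping the marked spots, a joint fit of all 24 arrays with slide as a fixed block, fits within slides 1 and 2, and fits without the arrays labelled sak1Δ.

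The sample channel was well above background for 90.46% to 99.43% of the spots and the reference channel for 87.33% to 98.34%. The share of spots left out was 15.65% to 41.62% on slide 4 and 1.354% to 13% on the other slides, and 4001 to 5058 genes had a value per array. The number of arrays limits the precision.

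The fits were tested on simulated data in which 200 genes were changed by known amounts. At a log2 change of 1, the share recovered was 80.5% for sak1Δ against wild type, 87.3% for fkh2Δ, 92.3% for sep1Δ, 83.1% for 12 h against 8 h and 90.8% for hydroxyurea. At a log2 change of 0.5 it was 37.3%, 53.8%, 44.3%, 40.9% and 28.8% in the same order. In the temperature fit, a log2 change of 2 was recovered for 46.0% of the genes between sak1-891 and wild type at 36 °C, 65.7% between temperatures and 0% of 67 genes for the difference of the responses. A log2 change of 1 was recovered there for 0% of 75 genes between the strains at 36 °C and 33.85% between temperatures. A shift of 0.4 added to the M phase list was recovered in each of 4 comparisons with no other list called. The simulated genes varied independently, with the same spread on every array of a fit and without a slide effect. The simulation thus does not test the list calls where genes vary together, nor comparisons in which some arrays are noisier than others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and random steps used the seeds 11, 12, 13 and 21.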

Results

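Expression was measured in germinating spores and in exponentially growing cells of fission yeast to ask which genes depend on Sak1, an RFX-family transcription factor, and how this relates to the forkhead factors Fkh2 and Sep1. Spores of sporulated heterozygous diploids, in which the deletion is marked with ura4+, were germinated in a medium where spores carrying ura4+ can grow. Wild-type ura4+ spores served as the control. Wild type and fkh2Δ were harvested at 6, 8, 10 and 12 h (4 arrays each), and sak1Δ and sep1Δ at 8, 10 and 12 h (3 arrays each). Each of these 4 genotypes was also harvested at 10 h in hydroxyurea, which blocks DNA replication (1 array each). A temperature-sensitive allele, sak1-891, and wild type were grown in rich medium at 26 °C (1 array each) and for 2 h and 4 h at 36 °C (2 arrays each). The median sample intensity was 3638 to 13470 on slide 4, which held the 4 sak1Δ germination arrays, and 8392 to 21760 on the other slides. There were no biological replicates of a genotype at one harvest.

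The transcript of the deleted gene was lower than in wild type at every harvest in each deletion, and it was closest to wild type in the arrays labelled sak1Δ. The fkh2 transcript in fkh2Δ was 44.5%, 38.0%, 34.9% and 23.3% of wild type at 6, 8, 10 and 12 h and 45.3% in hydroxyurea. The sep1 transcript in sep1Δ was 43.1%, 30.3% and 20.5% at 8, 10 and 12 h and 29.0% in hydroxyurea. The sak1 transcript in the arrays labelled sak1Δ was 74.2%, 76.9% and 86.5% of wild type at 8, 10 and 12 h and 73.7% in hydroxyurea. Over the fits, fkh2 fell by 1.47 in fkh2Δ (SE 0.153, adjusted p = 2.36e-05), sep1 fell by 1.68 in sep1Δ (SE 0.192, adjusted p = 3.03e-04) and sak1 fell by 0.39 in the arrays labelled sak1Δ (SE 0.111, adjusted p = 0.0235), all on the log2 scale. The sak1 call was lost without the sak1Δ hydroxyurea array (-0.36, adjusted p = 0.0586) and without the wild-type 10 h array (-0.39, adjusted p = 0.0591). Whether the sak1 probes lie within the deleted part of the gene is not known, so a remaining signal neither bears out nor contradicts the label. These arrays are therefore called the arrays labelled sak1Δ.

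**Figure D1:**
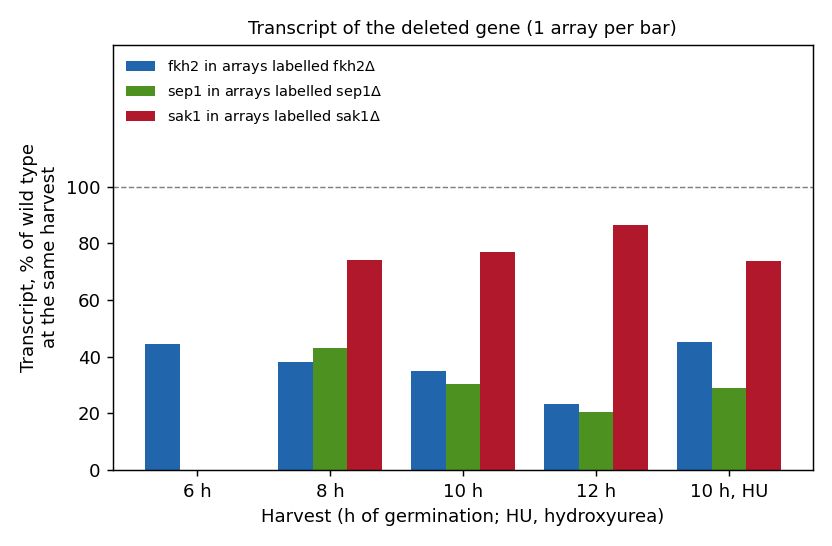
Transcript of the deleted gene as a percent of wild type at the same harvest (vertical axis) against harvest (horizontal axis), 1 array per bar, for fkh2 (blue), sep1 (green) and sak1 (red) in the arrays labelled with the deletion of that gene. The fkh2 and sep1 bars lie between 20.5% and 45.3%, and the sak1 bars between 73.7% and 86.5%.

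Genes of mitosis and cytokinesis were lower in the arrays labelled sak1Δ than in wild-type germinating spores. Of 4425 genes tested, 451 were higher and 490 lower, and 886 of these 941 had the same sign at 8, 10 and 12 h. At least a 2-fold difference was seen for 167 genes. Of the 25 M phase and cytokinesis genes tested, 10 fell, none rose, and 15 did not pass, and 12 fell when adjusted over the list alone. Lower genes were cdc15, encoding an F-BAR protein of the contractile ring (-1.38, SE 0.206, adjusted p = 8.77e-04), and the polo kinase gene plo1 (-0.96, SE 0.161, adjusted p = 0.00170). The mitotic inducer cdc25 (-0.78, adjusted p = 0.00230) and mid1, which places the division site (-0.71, adjusted p = 0.00170), also fell. The list mean was -0.41 (camera adjusted p = 2.11e-04), with adjusted p = 0.278 with an estimated correlation. Its median was -0.44, -0.52 and -0.35 at 8, 10 and 12 h and -0.21 in hydroxyurea, with 0, 0, 0.1 and 2.53 percent of random lists below it. The fkh2 and sep1 transcripts differed by 0.22 (adjusted p = 0.344) and -0.31 (adjusted p = 0.252), and neither passed.

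Among the 6 cell separation genes tested, all values were negative, and adg2 (-1.80, SE 0.428, adjusted p = 0.0106) and cfh4 (-0.69, adjusted p = 0.0233) fell, the same 2 genes when adjusted over the list alone. The list did not pass (mean -0.73, camera adjusted p = 0.0544). Of 16 MBF genes, 3 fell, msh6 of mismatch repair among them (-1.01, SE 0.215, adjusted p = 0.00593), and the list did not pass (mean -0.24, adjusted p = 0.0683). Mating regulators were lower: ste11, the master transcription factor of mating (-1.01, SE 0.145, adjusted p = 7.37e-04), mei2 (-1.07, adjusted p = 9.28e-04), ste4 (-1.26, adjusted p = 5.03e-04) and map1 (-0.78, adjusted p = 9.75e-04). In that list 6 of 16 genes fell and 2 rose, and it did not pass as a whole (adjusted p = 0.0586). The heat shock chaperones moved apart. The Hsp70 gene ssa1 (1.43, SE 0.130, adjusted p = 2.83e-05) and hsp104 (1.55, adjusted p = 5.03e-04) rose, while the mitochondrial chaperonin gene mcp60 (-1.05, adjusted p = 0.00695) and mas5 (-0.91, adjusted p = 0.0196) fell.

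The largest increases in the arrays labelled sak1Δ were in hry1 (3.35, SE 0.184, adjusted p = 2.82e-07), the hexose transporter gene ght6 (3.34, SE 0.392, adjusted p = 2.29e-04), pdc202 (3.32, SE 0.563, adjusted p = 0.00218), the protein kinase gene ppk31 (2.86, adjusted p = 3.38e-05), mug108 (2.70, adjusted p = 7.37e-04) and the alpha-galactosidase gene mel1 (2.65, adjusted p = 9.97e-04). Among the largest decreases were the phosphate transporter gene pho84 (-2.24, SE 0.214, adjusted p = 3.38e-05), the phosphofructokinase gene pfk1 (-1.94, SE 0.280, adjusted p = 8.77e-04) and the iron permease gene fip1 (-1.92, SE 0.246, adjusted p = 3.33e-04). The helicase genes tlh2 (-2.99, adjusted p = 3.44e-05) and tlh1 (at least 5.1-fold lower, adjusted p = 9.75e-04) were lower as well. They are near-identical subtelomeric copies, so their values are uncertain. Amino acid and pyrimidine synthesis genes were lower as a group (mean -0.32, camera adjusted p = 0.0175, adjusted p = 0.454 with an estimated correlation). Of its 23 genes 6 fell, the same number when adjusted over the list alone, with lys1 at -1.38 (adjusted p = 9.88e-04) and ura2 at -0.71 (adjusted p = 0.0127).

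All 4 arrays labelled sak1Δ lay on slide 4 and no wild-type germination array did, so slide and genotype cannot be separated within the germination arrays. A fit with slide as a random block called 616 genes, and the M phase list mean was -0.41 (adjusted p = 1.74e-04), the cell separation mean -0.74 (adjusted p = 0.0416) and the amino acid mean -0.32 (adjusted p = 0.0185). A random block cannot take an effect of slide 4 out of this contrast, nor out of those of sak1Δ against fkh2Δ and sep1Δ below. In a joint fit with the temperature arrays, 2 of which also lay on slide 4, and slide as a fixed block, 2 genes passed, 1 of them among the 941. The M phase list mean was then -0.37 (adjusted p = 0.00341), the cell separation mean -0.77 (adjusted p = 0.0605) and the amino acid mean -0.17 (adjusted p = 0.302). Iron uptake genes gave opposite signs, with a mean of -0.66 (7 genes, camera adjusted p = 0.0346, adjusted p = 0.454 with an estimated correlation), -0.67 with the random block (adjusted p = 0.0326), and 1.40 in the joint fit (adjusted p = 2.83e-06). The slide 4 effect that the joint fit takes out, estimated from the temperature arrays, had a mean of -2.09 over this list. In those arrays the list's median in sak1-891 minus wild type went from 0.56 at 2 h to -2.17 at 4 h. A strain difference that changes with hours enters that estimate, so the joint fit does not correct for slide alone. The iron uptake call was also lost without the sak1Δ 10 h array (-0.43, adjusted p = 0.103), the sak1Δ 12 h array (-0.59, adjusted p = 0.104), the wild-type 6 h array (-0.66, adjusted p = 0.0539) or the wild-type 12 h array (-0.60, adjusted p = 0.0775). Fitting only the groups compared gave 140 genes. The count of 941 fell to 393 without the wild-type 10 h array, 414 without the sak1Δ 10 h array, 499 without the wild-type hydroxyurea array and 588 without the wild-type 12 h array.

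In fkh2Δ germinating spores, genes of mitosis and cytokinesis were higher than in wild type. Of 5034 genes tested, 357 were higher and 396 lower, 673 of the 753 had the same sign at all 4 harvests without hydroxyurea, and 147 differed at least 2-fold. Of 27 M phase and cytokinesis genes, 15 rose, 1 fell (fkh2 itself) and 11 did not pass, and 19 rose and 2 fell when adjusted over the list alone. The septation gene etd1 (1.58, SE 0.158, adjusted p = 1.58e-05), slp1, an activator of the anaphase-promoting complex (1.58, SE 0.174, adjusted p = 6.40e-05), and plo1 (1.16, SE 0.148, adjusted p = 1.66e-04) rose. The list mean was 0.52 (camera adjusted p = 2.48e-08), with adjusted p = 0.0520 with an estimated correlation. Its median was 0.34, 0.38, 0.71 and 0.67 at 6, 8, 10 and 12 h and 0.33 in hydroxyurea, and at each harvest at least 99.96 percent of random lists lay below it. None of the 7 cell separation genes passed, and the list mean was 0.49 (adjusted p = 0.0666). The sak1 transcript was 0.36 higher (SE 0.102, adjusted p = 0.0283). That call was lost when any 1 of 6 arrays was left out, with the adjusted p at 0.0773 without the fkh2Δ 12 h array, 0.0771 without the fkh2Δ 10 h array, and 0.0572, 0.0644, 0.0778 and 0.0693 without the wild-type 8 h, 10 h, 12 h and hydroxyurea arrays.

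**Figure D2:**
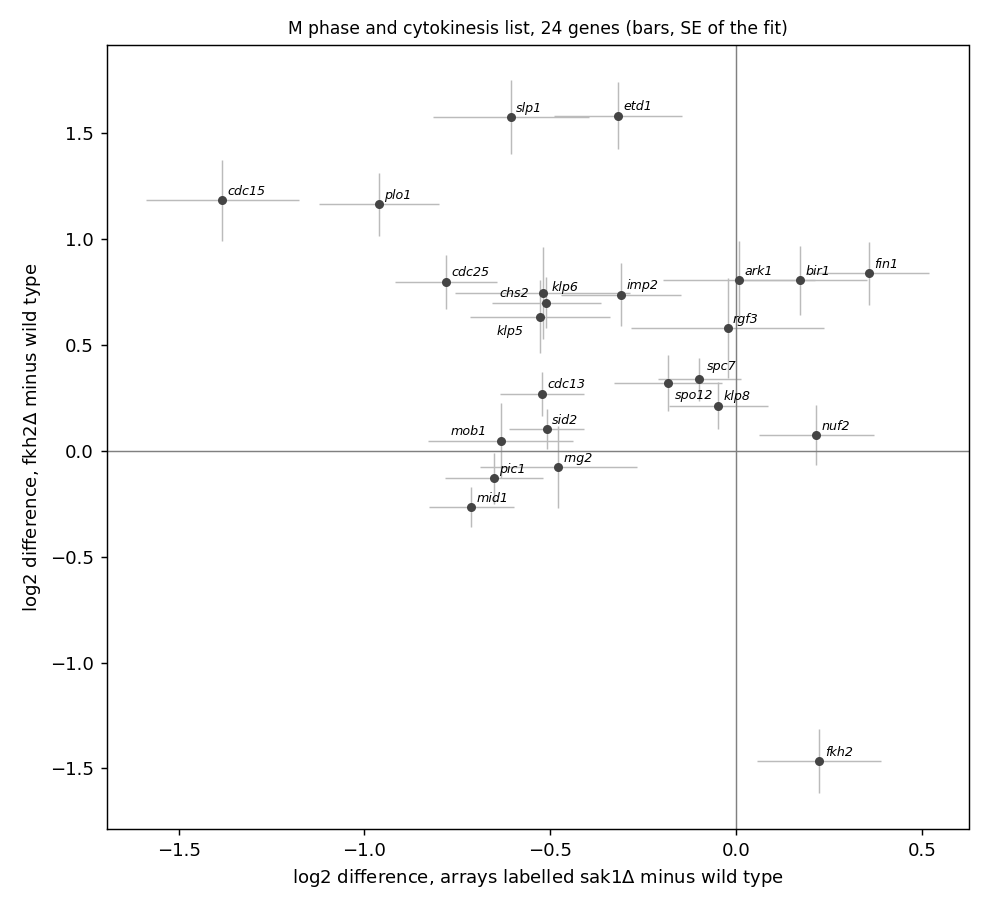
Log2 difference of 24 of the 25 M phase and cytokinesis genes tested in both fits, in the arrays labelled sak1Δ minus wild type (horizontal axis) and in fkh2Δ minus wild type (vertical axis), with bars showing the standard error of the fit. In all, 16 of the 24 genes drawn lie at the upper left, lower in the arrays labelled sak1Δ and higher in fkh2Δ. The gene deleted in fkh2Δ, fkh2, lies at the bottom.

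MBF genes were higher in fkh2Δ (mean 0.39, camera adjusted p = 2.20e-04, adjusted p = 0.407 with an estimated correlation). Of its 21 genes 5 rose, and 9 rose and 1 fell when adjusted over the list alone. Among them were pol1, encoding the catalytic subunit of DNA polymerase alpha (0.86, SE 0.115, adjusted p = 2.41e-04), and the Cdc2-inhibiting kinase gene mik1 (1.40, SE 0.249, adjusted p = 0.00228). Heat shock chaperones were higher (mean 0.44, camera adjusted p = 7.54e-04, adjusted p = 0.407 with an estimated correlation). Of 17 genes 4 rose, 6 when adjusted over the list alone, with hsp16 at 2.23 (SE 0.407, adjusted p = 0.00451) and ssa1 at 1.56 (SE 0.119, adjusted p = 1.76e-06). Sporulation genes were higher (mean 0.40, camera adjusted p = 0.0213, adjusted p = 0.407 with an estimated correlation), with 6 of 19 higher and 1 lower, and 8 higher and 3 lower when adjusted over the list alone. The meiotic septin gene spn7 (1.22, SE 0.123, adjusted p = 1.59e-05) and meu14 (2.27, SE 0.371, adjusted p = 0.00157) were among them. The call of that list was lost without the fkh2Δ 12 h array (0.34, adjusted p = 0.0524) and without the wild-type 10 h array (0.35, adjusted p = 0.0530). Amino acid and pyrimidine synthesis genes were lower (mean -0.43, camera adjusted p = 1.71e-04, adjusted p = 0.283 with an estimated correlation). Of its 30 genes 11 fell, and 13 fell and 1 rose when adjusted over the list alone, with the asparagine synthetase gene asn1 at -1.16 (adjusted p = 0.00280) and leu3 at -1.33 (adjusted p = 0.00451). The mating list did not pass (mean 0.09, adjusted p = 0.451), with 2 of 16 genes higher and 2 lower, and 3 and 2 when adjusted over the list alone. Its gene mei2 (1.17, adjusted p = 1.63e-04) and the Ras exchange factor gene ste6 (1.29, adjusted p = 0.00168) rose, whereas ste11 (-0.45, adjusted p = 0.0352) and map2 (-0.90, adjusted p = 0.0212) fell. The 2 lower calls were lost without any 1 of 8 and 7 arrays (adjusted p up to 0.111 and 0.0650).

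The largest increases in fkh2Δ were in SPAC186.02c (5.39, SE 0.266, adjusted p = 1.61e-07), pdc202 (4.35, SE 0.467, adjusted p = 4.99e-05), glm1 (3.77, SE 0.216, adjusted p = 1.61e-07), pal2 (3.67, SE 0.281, adjusted p = 1.76e-06), the proton pump gene pma2 (3.66, SE 0.509, adjusted p = 3.34e-04) and the subtelomeric tlh1 (3.50, adjusted p = 3.58e-06, uncertain as one of near-identical copies). The largest decreases were in the vitamin transporter gene vht1 (-2.01, SE 0.326, adjusted p = 0.00179), the dihydroxyacetone kinase gene dak2 (-1.92, SE 0.184, adjusted p = 1.61e-05), the maltase gene mal1 (-1.90, SE 0.151, adjusted p = 5.17e-06) and the acid phosphatase gene pho1 (-1.60, adjusted p = 0.00105). Fitted with slide as a fixed block, 827 genes passed, 741 of them among the 753. The means of the M phase, MBF, heat shock, sporulation and amino acid lists were then 0.52, 0.39, 0.44, 0.39 and -0.43. Within slide 1 (6 h, 8 h and hydroxyurea) they were 0.43, 0.28, 0.58, 0.28 (adjusted p = 0.233) and -0.41, and within slide 2 (10 h and 12 h) 0.65, 0.55, 0.23 (adjusted p = 0.0650), 0.54 and -0.46. Within slide 1, 86 genes passed, and within slide 2, 1331. The count of 753 fell to 439 without the fkh2Δ 10 h array and to 459, 473 and 461 without the wild-type 8 h, 10 h and hydroxyurea arrays.

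In sep1Δ germinating spores, chaperone genes were higher than in wild type. Of 5023 genes tested, 26 were higher and 10 lower, 36 in all, each with the same sign at 8, 10 and 12 h. Of 17 heat shock chaperone genes, 7 rose and none fell, and 13 rose when adjusted over the list alone. The list mean was 0.86 (camera adjusted p = 1.25e-22, adjusted p = 0.00801 with an estimated correlation). The Hsp70 gene ssa1 (1.72, SE 0.129, adjusted p = 8.05e-06), the mitochondrial hsp78 (1.45, SE 0.210, adjusted p = 0.00355), the co-chaperone gene wos2 (1.03, SE 0.146, adjusted p = 0.00254) and mdj1 (0.61, SE 0.0893, adjusted p = 0.00312) were among them. Against the same wild-type arrays, ssa1 also rose in the arrays labelled sak1Δ and, with hsp16, in fkh2Δ. The list mean was 0.44 in fkh2Δ and -0.08 in the arrays labelled sak1Δ. The small heat shock gene hsp16 rose by 2.33 (SE 0.444, adjusted p = 0.0379). Its call was lost without any 1 of 7 arrays, with the adjusted p at 0.0667, 0.167, 0.161 and 0.128 without the sep1Δ 8 h, 10 h, 12 h and hydroxyurea arrays and 0.149, 0.0687 and 0.0850 without the wild-type 8 h, 10 h and hydroxyurea arrays. None of the 7 cell separation genes passed over all genes tested, although all were negative and 4 fell when adjusted over the list alone (mean -0.93, camera adjusted p = 1.41e-05, adjusted p = 0.264 with an estimated correlation). The median of that list was -0.78, -1.10 and -1.85 at 8, 10 and 12 h and 0.02 in hydroxyurea.

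No M phase gene passed in sep1Δ over all genes tested. Of 27 such genes 26 were negative, 5 fell when adjusted over the list alone, and the list mean was -0.28 (camera adjusted p = 1.60e-06, adjusted p = 0.0622 with an estimated correlation). Among its members were slp1 (-0.80, adjusted p = 0.0861), the chitin synthase gene chs2 (-0.68, adjusted p = 0.0581) and the myosin gene myp2 (-0.61, adjusted p = 0.133). All 9 histone genes were negative with none past the threshold, also when adjusted over the list alone (mean -0.36, camera adjusted p = 9.33e-04, adjusted p = 0.211 with an estimated correlation). The MBF list (mean 0.13, camera adjusted p = 0.0375, adjusted p = 0.588 with an estimated correlation) lost its call without the sep1Δ 8 h array (0.10, adjusted p = 0.1505) or hydroxyurea array (0.12, adjusted p = 0.0550), or the wild-type 8 h (0.12, adjusted p = 0.0656), 12 h (0.11, adjusted p = 0.111) or hydroxyurea array (0.06, adjusted p = 0.274). The amino acid list (mean -0.19, camera adjusted p = 0.0120, adjusted p = 0.357 with an estimated correlation) lost it without the sep1Δ 8 h (-0.16, adjusted p = 0.0732) or 12 h array (-0.12, adjusted p = 0.195) or the wild-type hydroxyurea array (-0.11, adjusted p = 0.178). Neither list had a gene past the threshold, also when adjusted over the list alone.

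Besides the chaperones, the largest increases in sep1Δ were in SPAPB24D3.07c (2.46, SE 0.3996, adjusted p = 0.00636), SPAC977.14c (2.09, SE 0.158, adjusted p = 1.71e-05), SPCC663.08c (1.66, SE 0.161, adjusted p = 5.45e-05) and the glutathione transferase gene gst2 (1.24, SE 0.171, adjusted p = 0.00262). Lower were psu2 (-1.16, SE 0.128, adjusted p = 3.12e-04) and the galactokinase gene gal1 (-1.27, SE 0.207, adjusted p = 0.00636). Fitted with slide as a fixed block, 43 genes passed, 30 of them among the 36. The means of the M phase, cell separation, histone, heat shock, amino acid and MBF lists were then -0.31, -1.27, -0.41, 0.86, -0.18 and 0.06 (the last with adjusted p = 0.257). Within slide 1, which held a single sep1Δ array (8 h), they were -0.20, -0.79, -0.31, 0.89, -0.21 and 0.24, and within slide 2 -0.32, -1.48, -0.52, 0.80, -0.21 and 0.08. Within slide 2 limma called 73 genes, and within slide 1 it called 0, which with 1 sep1Δ array says little. A fit of only the groups compared gave 477 genes, all 36 among them. The count of 36 fell to 18 and 22 without the sep1Δ 10 h and 12 h arrays and to 23, 20 and 22 without the wild-type 8 h, 10 h and hydroxyurea arrays.

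**Figure D3:**
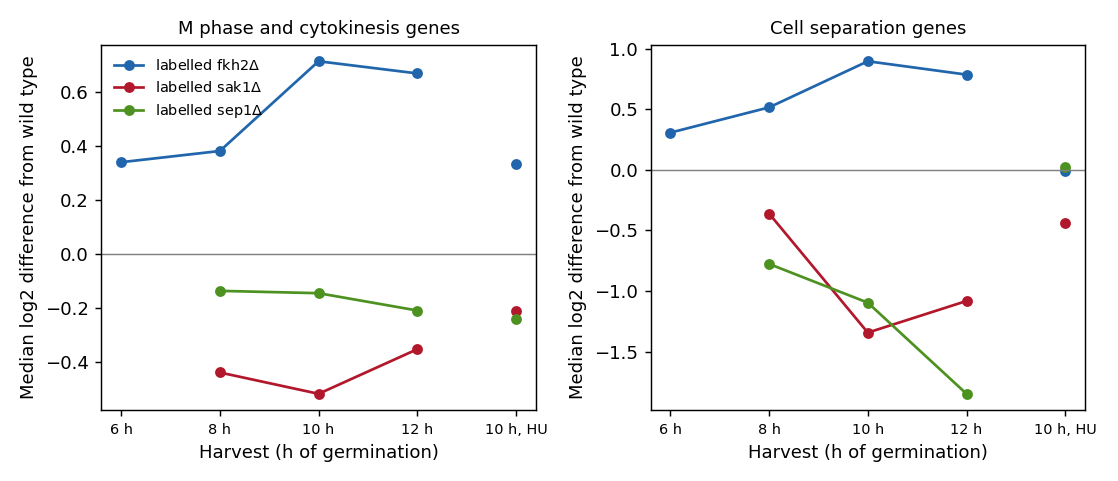
Median log2 difference from wild type at the same harvest (vertical axis) of the M phase and cytokinesis list (left) and the cell separation list (right) against harvest (horizontal axis), 1 array of each genotype per point, for fkh2Δ (blue) and the arrays labelled sak1Δ (red) and sep1Δ (green). The M phase medians lie between 0.33 and 0.71 in fkh2Δ and below 0 at each harvest in both other deletions.

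The differences of the 3 deletions from wild type share the wild-type arrays, so some likeness arises without any effect. In all 3, ssa1 was higher and the amino acid list lower. The part of the shared wild-type arrays in this was not tested. Across 4423 genes, the sak1Δ and fkh2Δ differences correlated with r = 0.241, against 0.450 on average in 50 simulations of unchanged groups, and with r = 0.180 when the wild-type arrays were split between the comparisons. Their covariance was 0.0486, against 0.0168 simulated, and 0.0439 with split arrays. Both called 62 genes higher and 60 lower, where independent lists would share 31.5 and 37.9. Another 28 genes were lower in the arrays labelled sak1Δ and higher in fkh2Δ, and 22 the other way round, where independent lists would give 34.2 and 34.9. The sak1Δ and sep1Δ differences correlated with r = 0.104 (0.458 simulated, 0.0583 split) with a covariance of 0.0121 (0.0186 simulated), and shared 11 higher and 3 lower genes (2.45 and 1.11 for independent lists). For fkh2Δ and sep1Δ the correlation was 0.279 (0.456 simulated, 0.222 split) and the covariance 0.0299 (0.0168 simulated), with 9 and 6 genes shared (1.85 and 0.787 for independent lists). These correlations are across genes, which are not independent replicates. Independent lists share no wild-type arrays, so shared genes beyond their number may come in part from those arrays. The simulated correlations come from groups without effects, so a lower observed r does not show less likeness than the shared arrays give.

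The arrays labelled sak1Δ and fkh2Δ were compared directly to test whether the deletions differ in mitotic gene expression. Of 4416 genes tested, 737 were higher and 678 lower in the arrays labelled sak1Δ, 1336 of the 1415 with the same sign at 8, 10 and 12 h. Of 25 M phase genes 20 were lower and 1 higher (fkh2 itself, 1.69), and 21 lower and 1 higher when adjusted over the list alone. The list mean was -0.93 (camera adjusted p = 5.83e-11, adjusted p = 0.0182 with an estimated correlation). The values were -2.56 for cdc15 (SE 0.206, adjusted p = 2.06e-06), -2.12 for plo1 (SE 0.161, adjusted p = 1.28e-06), -1.90 for etd1 (SE 0.172, adjusted p = 6.25e-06) and -1.58 for cdc25 (SE 0.138, adjusted p = 4.38e-06). MBF genes were lower (9 of 16, the same number when adjusted over the list alone; mean -0.70, camera adjusted p = 1.13e-04, adjusted p = 0.348 with an estimated correlation), with msh6 at -1.56, mik1 at -1.74 and pol1 at -1.06. Outside the lists, meu6 (-3.48, SE 0.333, adjusted p = 1.10e-05) was lower and the glucanase gene bgl2 (2.61, SE 0.266, adjusted p = 2.06e-05) higher. The subtelomeric tlh2 (-6.27) and tlh1 (at least 62.7-fold lower) were far lower, with the uncertainty of near-identical copies. With slide as a random block 1115 genes passed, and the M phase and MBF means were -0.93 and -0.70. In the joint fit with slide as a fixed block 7 genes passed, and these means were -0.89 (adjusted p = 2.35e-09) and -0.57 (adjusted p = 0.00528). The count was 515 with only the groups compared, and fell to 826 without the sak1Δ 10 h array and to 781 without the fkh2Δ 10 h array.

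Other list differences between the arrays labelled sak1Δ and fkh2Δ lost their calls without some single arrays, and each was lost with an estimated correlation (adjusted p = 0.348 for cell separation, heat shock, mating and iron uptake, 0.654 for ribosomal proteins). Cell separation genes were lower (4 of 6, 5 when adjusted over the list alone; mean -1.18, camera adjusted p = 0.00798), with adg2 at -2.54 (adjusted p = 6.96e-04), agn1 at -1.18 (adjusted p = 0.0172), mid2 at -1.02 (adjusted p = 0.0108) and cfh4 at -0.95 (adjusted p = 0.00274). That call was lost without the sak1Δ 8 h (adjusted p = 0.145), 10 h (0.0893) or hydroxyurea array (0.0724), or the fkh2Δ 8 h (0.163), 10 h (0.0826) or hydroxyurea array (0.0838). Heat shock genes (5 of 14 lower and 1 higher, the same numbers when adjusted over the list alone; mean -0.39, adjusted p = 0.0291) lost it without the sak1Δ 8 h (0.101) or 12 h array (0.0711) or the fkh2Δ 8 h (0.0907) or hydroxyurea array (0.0578). Their members ssa2 (-1.49, adjusted p = 5.02e-04) and hsp104 (1.08, adjusted p = 0.00195) went opposite ways. Mating genes (6 of 16 lower and 2 higher, 7 and 3 when adjusted over the list alone; mean -0.36, adjusted p = 0.0399) lost it without the sak1Δ 8 h (0.101), fkh2Δ 10 h (0.0518) or fkh2Δ hydroxyurea array (0.0813), with mei2 at -2.24 and ste4 at -1.36. Ribosomal protein genes (12 of 92 lower and 1 higher, 11 and 1 when adjusted over the list alone; mean -0.24, adjusted p = 0.00816) lost it without the sak1Δ 8 h (0.125) or fkh2Δ 8 h array (0.299). Their mean turned from -0.83 at 8 h and -0.38 at 10 h to 0.19 at 12 h and 0.14 in hydroxyurea. Iron uptake genes (4 of 7 lower and 1 higher, 5 and 1 when adjusted over the list alone; mean -0.55, adjusted p = 0.0488) lost it without any of the 4 arrays labelled sak1Δ (0.0610, 0.0893, 0.0846 and 0.0724 for 8 h, 10 h, 12 h and hydroxyurea) or the fkh2Δ 10 h (0.0862), 12 h (0.106) or hydroxyurea array (0.0890). Slide as a random block gave these lists means of -1.19, -0.39, -0.36, -0.24 and -0.55 (the last with adjusted p = 0.0506). In the joint fit with slide as a fixed block they were -1.22, -0.20 (adjusted p = 0.584), -0.15 (adjusted p = 0.573), -0.69 and 1.51.

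Against sep1Δ, chaperone genes and several M phase genes were lower in the arrays labelled sak1Δ. Of 4411 genes tested, 611 were higher and 587 lower, 1128 of the 1198 with the same sign at 8, 10 and 12 h. Of 14 heat shock genes 8 were lower and none higher, 9 when adjusted over the list alone (mean -0.86, camera adjusted p = 1.31e-05, adjusted p = 0.273 with an estimated correlation). The values were -1.83 for ssa2 (SE 0.245, adjusted p = 4.37e-04), -1.79 for hsp78 (SE 0.238, adjusted p = 4.67e-04), -1.78 for mas5 (SE 0.248, adjusted p = 5.90e-04) and -1.31 for wos2 (SE 0.1503, adjusted p = 2.22e-04). Of 24 M phase genes 6 were lower and 1 higher, the same numbers when adjusted over the list alone, among them cdc15 (-1.30, SE 0.211, adjusted p = 0.00108), cdc25 (-0.70, adjusted p = 0.00396), plo1 (-0.67, adjusted p = 0.00997) and the cyclin gene cdc13 (-0.52, adjusted p = 0.00637). That list did not pass (mean -0.15, adjusted p = 0.174). Of 16 MBF genes 6 were lower, the same number when adjusted over the list alone (mean -0.37, camera adjusted p = 0.0130, adjusted p = 0.599 with an estimated correlation), with cdc22, encoding a subunit of ribonucleotide reductase, at -1.03 and cdt2 at -1.08. The largest differences outside the lists were in hry1 (4.04, adjusted p = 2.88e-08), pdc202 (3.52, adjusted p = 0.00130) and the enolase gene eno101 (-2.44, adjusted p = 2.55e-04). The sak1 transcript was 0.42 lower (SE 0.114, adjusted p = 0.0158), a call lost without the sep1Δ hydroxyurea array (-0.32, adjusted p = 0.0656).

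Ribosomal protein genes (mean -0.25, camera adjusted p = 0.0130, adjusted p = 0.735 with an estimated correlation) and iron uptake genes (5 of 7; mean -0.84, camera adjusted p = 0.00491, adjusted p = 0.273 with an estimated correlation) were also lower in the arrays labelled sak1Δ than in sep1Δ. Of 91 ribosomal protein genes 14 were lower and 2 higher, with rps902 at -1.13 (adjusted p = 0.00557), and 13 lower and 1 higher when adjusted over the list alone, and for iron uptake these numbers were 6 and 1. The ribosomal protein call was lost without the sak1Δ 8 h array (-0.21, adjusted p = 0.162), and the MBF call without the sak1Δ 12 h array (-0.29, adjusted p = 0.0902). With slide as a random block 842 genes passed, and the means of the heat shock, MBF, ribosomal protein and iron lists were -0.85, -0.36, -0.25 and -0.84. In the joint fit with slide as a fixed block 2 genes passed, and these means were -0.68 (adjusted p = 0.00808), -0.13 (adjusted p = 0.470), -0.70 and 1.22. With only the groups compared 406 genes passed. The count of 1198 fell to 525 without the sak1Δ 10 h array and to 660, 446, 781 and 671 without the sep1Δ 8 h, 10 h, 12 h and hydroxyurea arrays.

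Between 8 h and 12 h of germination, few genes changed over the 4 genotypes. Of 5008 genes tested, 17 were higher and 2 lower at 12 h, each with the same sign in all 4 genotypes. The galactose pathway genes gal1 (1.55, SE 0.212, adjusted p = 0.00402) and gal10 (1.41, SE 0.162, adjusted p = 0.00102), dak2 (1.47, SE 0.190, adjusted p = 0.00402) and mug14 (2.08, SE 0.164, adjusted p = 3.68e-05) rose. The 2 lower genes were fra2 (-1.31, adjusted p = 0.0368) and SPCC16C4.21 (-0.92, adjusted p = 0.0303). Cell separation genes were higher as a group (mean 0.57, camera adjusted p = 0.0473, adjusted p = 0.764 with an estimated correlation), with none of 7 past the threshold, also when adjusted over the list alone, and the glucanase gene eng1 at 1.22 (adjusted p = 0.488). Single pairs of arrays gave list means of 0.87 in wild type, 1.23 in fkh2Δ, -0.42 in the arrays labelled sak1Δ (3 genes measured) and -0.16 in sep1Δ, and these were not tested against each other. In wild type alone the list's median was -0.81 at 6 h, 0.72 at 10 h and 1.05 at 12 h relative to 8 h. The 8 h and 12 h arrays lay on slides 1 and 2 in wild type, fkh2Δ and sep1Δ and both on slide 4 in sak1Δ. The list mean was 0.43 with slide as a random block (adjusted p = 0.106) and -0.50 as a fixed block (adjusted p = 0.0963), when 10 genes passed, 5 of them among the 19.

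The number of genes past the threshold between 8 h and 12 h depended on single arrays. It stayed at 19 without the sak1Δ 12 h array and was 3 with only the groups compared. The count fell to 4 without the wild-type 8 h or 12 h array, to 6 without the fkh2Δ 8 h or sep1Δ 12 h array, and to 9, 11 and 8 without the fkh2Δ 12 h, sak1Δ 8 h and sep1Δ 8 h arrays. The cell separation call was lost without the 8 h or 12 h array of wild type (0.27, adjusted p = 0.647, and 0.22, adjusted p = 0.617), fkh2Δ (0.16, adjusted p = 0.621, and 0.02, adjusted p = 0.905) or sep1Δ (0.34, adjusted p = 0.502, and 0.52, adjusted p = 0.195). The fra2 call was lost without the 8 h array of wild type (adjusted p = 0.1), fkh2Δ (0.157) or sak1Δ (0.199), or the 12 h array of wild type (0.0961), fkh2Δ (0.0838), sak1Δ (0.122) or sep1Δ (0.0781). That of SPCC16C4.21 was lost without the 8 h array of any genotype (0.1, 0.120, 0.153 and 0.0608 for wild type, fkh2Δ, sak1Δ and sep1Δ) or the 12 h array of wild type (0.136) or sep1Δ (0.169).

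Hydroxyurea raised the genes of the G1/S transition and the histone genes. Of 4933 genes tested, 37 were higher and 18 lower with hydroxyurea at 10 h, each with the same sign in all 4 genotypes. Of 21 MBF genes 13 rose, 17 when adjusted over the list alone (mean 0.93, camera adjusted p = 1.71e-22, adjusted p = 0.0262 with an estimated correlation). The replication licensing gene cdc18 (1.81, SE 0.293, adjusted p = 0.00744), cdt2 (1.79, SE 0.261, adjusted p = 0.00353), cdc22 (1.64, SE 0.239, adjusted p = 0.00353), the cyclin gene cig2 (1.36, SE 0.193, adjusted p = 0.00457) and yox1, encoding a repressor of MBF genes (1.11, SE 0.112, adjusted p = 7.07e-04), were among them. The cohesin gene psm3 (1.10, SE 0.157, adjusted p = 0.00353) and hop1 (2.03, SE 0.286, adjusted p = 0.00353) also rose. Of 9 histone genes 5 rose, 7 when adjusted over the list alone, with htb1 at 1.31 (SE 0.180, adjusted p = 0.00353; mean 0.91, camera adjusted p = 1.51e-10, adjusted p = 0.0262 with an estimated correlation). Of 119 ribosomal protein genes 118 were negative, 8 fell, and 62 fell when adjusted over the list alone, with rps1402 at -1.17 (SE 0.178, adjusted p = 0.0146) and rpl1702 at -0.95 (adjusted p = 0.0373; mean -0.61, camera adjusted p = 1.26e-35, adjusted p = 0.124 with an estimated correlation).

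Cell separation genes were lower with hydroxyurea (mean -0.81, camera adjusted p = 0.00113, adjusted p = 0.302 with an estimated correlation), with none of 6 past the threshold and 3 when adjusted over the list alone. Single pairs gave list means of -1.37 in wild type and -2.05 in fkh2Δ, whose paired arrays lay on different slides, and 0.42 in the arrays labelled sak1Δ and 0.06 in sep1Δ, whose pairs shared a slide. The genotypes were not tested against each other here. The value of agn1 (-1.23, adjusted p = 0.115) passed without the sep1Δ hydroxyurea array (-1.46, adjusted p = 0.0449). The cell separation call was lost without the fkh2Δ hydroxyurea array (-0.38, adjusted p = 0.154), the wild-type 10 h array (-0.59, adjusted p = 0.0583) or the fkh2Δ 10 h array (-0.52, adjusted p = 0.0762). Sporulation (mean 0.25, camera adjusted p = 0.00830), iron uptake (0.34, adjusted p = 0.0215) and core stress genes (0.24, adjusted p = 0.0240) were higher, with adjusted p = 0.302, 0.302 and 0.544 with an estimated correlation. Each of these lists had 1 gene past the threshold when adjusted over the list alone. The sporulation call was lost without the wild-type 10 h array (0.23, adjusted p = 0.0583) and the iron call without the sak1Δ hydroxyurea (0.35, adjusted p = 0.0930) or 10 h array (0.22, adjusted p = 0.274). The core stress call was lost without the wild-type (0.13, adjusted p = 0.2503) or sep1Δ hydroxyurea array (0.17, adjusted p = 0.228) or the fkh2Δ (0.15, adjusted p = 0.126) or sep1Δ 10 h array (0.23, adjusted p = 0.0587).

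The hydroxyurea arrays of wild type and fkh2Δ lay on slide 1 and their 10 h arrays on slide 2, whereas both sep1Δ arrays lay on slide 2 and both sak1Δ arrays on slide 4. A fixed block of slide left 18 genes, 15 of them among the 55, and the means of the MBF, histone and ribosomal protein lists were 1.06, 1.05 and -0.54. Those of the cell separation, sporulation, iron and core stress lists were then -0.08 (adjusted p = 0.568), 0.20 (adjusted p = 0.0985), 0.33 and 0.12 (adjusted p = 0.362). Within slide 2, where the sep1Δ hydroxyurea array was the only one with hydroxyurea, 79 genes passed. The list means, which describe that array and not the 4 genotypes, were, in the same order, 0.99, 1.23, -0.66, 0.15 (adjusted p = 0.466), 0.24, 0.10 (adjusted p = 0.520) and 0.43. Slide 1 held no matched pair. The count of 55 fell to 20 with only the groups compared, to 16, 18 and 19 without the hydroxyurea arrays of wild type, fkh2Δ and sep1Δ and to 13, 12 and 11 without their 10 h arrays, and rose to 84 and 85 without the sak1Δ hydroxyurea and 10 h arrays.

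At 36 °C, few genes passed the threshold between sak1-891 and wild-type cells. The fit had little power, as it recovered 0% of simulated log2 changes of 1 and 46.0% of those of 2. Of 4266 genes tested, 2 were higher and 17 lower, each at both 2 h and 4 h and each at least 2-fold. Of 7 cell separation genes, all negative, the glucanase gene eng1 fell (-1.97, SE 0.251, adjusted p = 0.0431), and all 7 fell when adjusted over the list alone (mean -1.40, camera adjusted p = 7.51e-14, adjusted p = 0.496 with an estimated correlation). The glucanase gene agn1 (-1.45, adjusted p = 0.0659), adg3 (-1.64, adjusted p = 0.0782) and adg1 (-1.10, adjusted p = 0.313) did not pass. The list's median was -0.96 at 2 h and -1.75 at 4 h, against -0.32 at 26 °C. The M phase list was lower (mean -0.38, camera adjusted p = 1.75e-05, adjusted p = 0.419 with an estimated correlation), with none of 25 genes past the threshold and 8 lower and 1 higher when adjusted over the list alone. Its members myp2 (-1.68, adjusted p = 0.0610), slp1 (-1.32, adjusted p = 0.0674) and plo1 (-1.27, adjusted p = 0.142) did not pass. The higher genes were the marker ura4 (8.67, SE 0.451, adjusted p = 0.00177) and mal1 (1.87, SE 0.186, adjusted p = 0.0183). The size of the ura4 value is uncertain, as its wild-type signal was dim at 2 h and not well above background at 4 h. The ura4 signal was 0.158% to 0.432% of the reference in the wild-type temperature strain and 97.6% to 115% in sak1-891. Lower were pho84 (-5.80, SE 0.252, adjusted p = 0.00116) and pho1 (-3.19, SE 0.315, adjusted p = 0.0183), and so were the glucanosyltransferase gene gas1 (-3.08, adjusted p = 0.0431), gdt1 (at least 22.4-fold lower, adjusted p = 0.0134) and the subtelomeric SPAC186.06 (at least 4.9-fold lower, adjusted p = 0.0134).

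All sak1-891 arrays lay on slide 3, which held no other array, so slide and strain cannot be told apart in this comparison, and a random block could not be fitted. With hours at 36 °C as a replicate block (1 residual degree of freedom), agn1, adg3, myp2, slp1 and plo1 passed. The lists with small shifts between sak1-891 and wild type at 36 °C, MBF and mating, had no gene past the threshold, also when adjusted over the list alone. The MBF list (mean 0.20, camera adjusted p = 0.00452, adjusted p = 0.694 with an estimated correlation) lost its call without the wild-type 2 h (0.13, adjusted p = 0.121) or sak1-891 2 h array (0.09, adjusted p = 0.308). The mating list (mean -0.27, camera adjusted p = 0.0206, adjusted p = 0.694 with an estimated correlation) lost it without the wild-type 4 h (-0.02, adjusted p = 0.778) or sak1-891 2 h array (-0.12, adjusted p = 0.289). Without the wild-type 2 h array 66 genes passed in place of 19, among them agn1 (-1.59, adjusted p = 0.0101), adg3 (-1.95, adjusted p = 0.00282), adg1 (-1.39, adjusted p = 0.0300), myp2 (-1.42, adjusted p = 0.0150), slp1 (-1.45, adjusted p = 0.0135) and plo1 (-1.52, adjusted p = 0.0136). Without the wild-type 4 h array 40 genes passed, agn1 (-1.32, adjusted p = 0.0455), adg3 (-1.33, adjusted p = 0.0474) and myp2 (-1.94, adjusted p = 0.00383) among them. Without the sak1-891 4 h array 34 passed, myp2 (-1.73, adjusted p = 0.0338) among them, and agn1 passed without the sak1-891 2 h array (-1.61, adjusted p = 0.0466). All 19 genes passed in each of the fits without an array of wild type or the sak1-891 4 h array.

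On the mean of both strains, the shift to 36 °C raised chaperone genes and lowered iron uptake genes. Of 4266 genes tested, 75 were higher and 48 lower at 36 °C, and 112 of these 123 differed at least 2-fold. Of 10 heat shock genes 6 rose, 9 when adjusted over the list alone (mean 1.75, camera adjusted p = 1.64e-08, adjusted p = 0.288 with an estimated correlation), with hsp16 at 4.14 (SE 0.249, adjusted p = 0.00286), ssa1 at 2.85 (SE 0.168, adjusted p = 0.00286) and the Hsp90 co-chaperone gene aha1 at 2.08 (SE 0.203, adjusted p = 0.0120). The DNAJ gene psi1 (3.06, SE 0.212, adjusted p = 0.00410) and gal10 (3.17, SE 0.426, adjusted p = 0.0243) rose too. Of 6 iron uptake genes 3 fell, 4 when adjusted over the list alone (mean -2.13, camera adjusted p = 4.99e-04, adjusted p = 0.404 with an estimated correlation), with the siderophore transporter gene str3 at -3.92 (adjusted p = 0.0395), the permease gene fip1 at -3.14 (adjusted p = 0.0311) and the oxidoreductase gene fio1 at -2.40 (adjusted p = 0.0397). In single arrays the iron uptake median in sak1-891 minus wild type was -0.66 at 26 °C, 0.56 at 2 h and -2.17 at 4 h. The mean of -2.13 thus joins strains that differed in these genes. Of 7 cell separation genes 3 fell, and all 7 when adjusted over the list alone (mean -1.04, camera adjusted p = 1.77e-05, adjusted p = 0.404 with an estimated correlation), with eng1 at -1.44 (SE 0.217, adjusted p = 0.0293) and agn1 at -1.15 (SE 0.182, adjusted p = 0.0309). At 2 h and 4 h the mean of that list was -0.77 and -0.11 in wild type and -1.57 and -1.69 in sak1-891. The stress genes tps1, for trehalose synthesis (1.70, adjusted p = 0.0264), and hsp9 (1.78, adjusted p = 0.0325) rose while the sulfiredoxin gene srx1 fell (-1.57, adjusted p = 0.0264), and the core stress list did not pass (mean 0.27, adjusted p = 0.159).

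Further lists shifted at 36 °C, each lost with an estimated correlation (adjusted p = 0.404, or 0.421 for ribosomal proteins), a test with 2 residual degrees of freedom here. They were ribosomal proteins (mean -0.39, camera adjusted p = 4.83e-06), amino acid synthesis (-0.31, adjusted p = 0.00433), histones (-0.58, adjusted p = 0.00675), ribosome biogenesis (-0.28, adjusted p = 0.0189) and sporulation (0.38, adjusted p = 0.0189). Among the sporulation genes spn7 (1.79, adjusted p = 0.0293) and spo6 (1.64, adjusted p = 0.0343) rose, and 4 rose and 1 fell when adjusted over the list alone. Of the histone genes hta2 fell (-1.62, adjusted p = 0.0241), and 2 fell when adjusted over the list alone. No gene of the other 3 lists passed, also when adjusted over the list alone. The biogenesis and sporulation calls were lost without the wild-type 4 h array (-0.22, adjusted p = 0.127, and 0.35, adjusted p = 0.0565). With slide as a fixed block 778 genes passed, all 123 among them, and the means of the heat shock, cell separation, iron, ribosomal protein, amino acid and histone lists were 1.75, -1.20, -2.42, -0.42, -0.38 and -0.65. Those of the biogenesis and sporulation lists were -0.22 (adjusted p = 0.122) and 0.35 (adjusted p = 0.0569). No slide held arrays of both temperatures of both strains. Without the wild-type 2 h, wild-type 4 h and sak1-891 4 h arrays 417, 774 and 208 genes passed.

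No gene passed for a difference of the 36 °C response between sak1-891 and wild type in limma (4266 genes tested, 119 with an unadjusted p under 0.05). The values were -1.74 for agn1, -1.44 for adg1, -1.29 for eng1 and -2.36 for myp2, each with adjusted p = 0.983. With hours at 36 °C as a replicate block a few genes passed. Of the lists, 4 passed with the preset correlation and none with an estimated one (adjusted p = 0.511 for each of the 4). Each strain had 1 array at 26 °C, so the spread in this fit comes only from the 36 °C arrays, which differ in hours. Cell separation genes had a more negative response in sak1-891 (mean -1.19, camera adjusted p = 5.24e-07), with 1 of 7 lower when adjusted over the list alone, as had histones (-0.88, adjusted p = 1.72e-04). Amino acid synthesis (0.34, adjusted p = 0.00459) and heat shock genes (0.43, adjusted p = 0.0469) had a more positive one. These 3 lists had no gene past the threshold when adjusted over the list alone. With slide as a fixed block the means were -0.86, -0.75, 0.47 and, for heat shock, 0.43 (adjusted p = 0.133). The amino acid call was lost without the wild-type 2 h array (0.20, adjusted p = 0.0511), and the heat shock call without the wild-type 4 h (0.43, adjusted p = 0.128) or sak1-891 2 h array (0.38, adjusted p = 0.115). Without each of the wild-type 4 h and sak1-891 2 h arrays 1 gene passed.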

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

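The tests of the slide 4 trend over all genes, of RNA from spores that did not germinate and of mislabelled arrays, the splits within matched pairs, and the fits with the marked spots kept, with slide in a joint fit and within slides, were chosen after the results were seen.

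In the wild-type germination group the 12 h array stood apart in the mean of the heat shock list, at 0.28 against -0.14 to -0.11 on the 3 other arrays. The fkh2Δ 10 h array stood apart in the share of spots left out, at 10.1% against 3.57% to 4.61%. Among 40 groups of 4 values tested, 2 stood apart, and chance flags about 1 in 20.

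The tested contrasts between deletions called 1415 genes between the arrays labelled sak1Δ and fkh2Δ and 1198 between the arrays labelled sak1Δ and sep1Δ. All arrays labelled sak1Δ lay on slide 4 and no fkh2Δ or sep1Δ array did, so slide and genotype cannot be separated in either contrast. Few genes passed in the joint fit with slide as a fixed block. The list means that differed between the arrays labelled sak1Δ and fkh2Δ were -0.93 for M phase (adjusted p = 0.0182 with an estimated correlation), -1.18 for cell separation, -0.70 for MBF, -0.39 for heat shock, -0.36 for mating and -0.55 for iron uptake (adjusted p = 0.348 with an estimated correlation for each of these 5) and -0.24 for ribosomal proteins (adjusted p = 0.654). Between the arrays labelled sak1Δ and sep1Δ they were -0.37 for MBF (adjusted p = 0.599), -0.86 for heat shock (adjusted p = 0.273), -0.25 for ribosomal proteins (adjusted p = 0.735) and -0.84 for iron uptake (adjusted p = 0.273), each with an estimated correlation. For the 36 °C response of sak1-891 against wild type, the list means called with the preset correlation were -1.19 for cell separation, -0.88 for histones, 0.43 for heat shock and 0.34 for amino acid synthesis. None of them passed with an estimated correlation (adjusted p = 0.511 for each), and no gene passed.

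The M phase list was lower in the arrays labelled sak1Δ by a mean of 0.41 on the log2 scale, and these arrays shared slide 4 and its scan session. Across genes, the difference of these arrays from wild type correlated by 0.167 with the slide 4 effect estimated from the temperature arrays. That estimate comes from single arrays of both strains at 2 h and 4 h. Its noise, and any strain difference that changed with hours, enter it, so a low correlation decides nothing. The loss of marked spots is argued against as the whole cause, since the mean with them kept was -0.37 (SE 0.0858, camera adjusted p = 4.18e-04). The slide effect on the M phase list itself was -0.12 (SE 0.0767, 25 genes), and with slide in a joint fit the mean was -0.37 (adjusted p = 0.00341), all 10 called M phase genes stayed negative, and the median standard error over all genes tested rose from 0.159 to 0.471. That slide effect, on which the joint fit also rests, comes from few arrays of other cells in another medium. An effect of slide 4 on germinating cells thus cannot be told apart from the genotype. A dependence of mitotic genes on Sak1 may remain as the biological explanation, and it needs arrays of both genotypes on one slide.

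The sak1 transcript stayed at 73.7% to 86.5% of wild type in the arrays labelled sak1Δ, while fkh2 and sep1 fell further in their deletions. RNA of spores that did not germinate could keep the transcript, and it would then decline as deletion spores grow, as the differences of fkh2 (-0.71 from 8 h to 12 h) and sep1 (-1.07) did, but sak1 changed by 0.22 (SE 0.322), which is too uncertain to decide. Mislabelled arrays are not excluded, as sak1 was lower in 4 of 4 harvests with an adjusted p = 0.0235, but on a slide shared with no wild-type germination array, and sak1 could not be tested with slide in the joint fit. Probes outside the deleted part could also keep a signal, and their positions are not in the files. These explanations cannot be told apart here.

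The M phase list went down in the arrays labelled sak1Δ and up in fkh2Δ. Slower or faster progress through germination, read from the change between 8 h and 12 h in the genotypes outside each contrast, stays open. The correlations across genes were 0.0721 for the arrays labelled sak1Δ and -0.112 for fkh2Δ. Both lay where the limits set beforehand would count against this explanation. However, only 19 of 5008 genes changed with time past the threshold. How well that change measures progress is thus not known, and the question was left undecided. The M phase median of wild type itself was -0.26 at 6 h, 0.02 at 10 h and -0.01 at 12 h relative to 8 h. The 0.71 and 0.67 of fkh2Δ above wild type at 10 h and 12 h thus lay beyond the wild-type course in these hours, although later hours were not measured. The cell separation median rose with time in wild type and at 8, 10 and 12 h was lower in the arrays labelled sak1Δ (not at 10 h with the brightest probe) and higher in fkh2Δ, but it was lower in sep1Δ too. Slide is argued against for fkh2Δ, whose lower within-slide mean was 0.43 (SE 0.114). For the arrays labelled sak1Δ it stays open, as above. A repressing role of Fkh2 and an activating role of Sak1 on shared genes is therefore only a hypothesis, and arrays of the double deletion beside both single deletions on one slide would test it.

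Other splits of the same arrays were counted to ask whether chance can be excluded. For sak1Δ against wild type, 1 of 100 splits drawn from 126 gave as many genes, the real one with 941. The highest other split gave 755 and differs from the real one only in where the wild-type 6 h array falls. The real split is also the split by slide 4. For fkh2Δ it was 1 of 100 (753, the highest other reaching 49.9% of that), for sep1Δ 1 of 100 (36, highest other 30, which again differs in the wild-type 6 h array) and for the arrays labelled sak1Δ against fkh2Δ 1 of 100 (1415, highest other 1016). For the arrays labelled sak1Δ against sep1Δ it was 1 of 35 (1198, highest other 9), for 12 h against 8 h 1 of 35 (19, highest other 0) and for hydroxyurea 1 of 35 (55, highest other 27, which swaps the pair of arrays labelled sak1Δ). These splits mix harvests or genotypes, while the fit matches arrays by them, so a share under 0.05 of them does not settle the question. Splits that swap arrays only within matched pairs number 16 for fkh2Δ against wild type and 8 for each of the others, too few for a share under 0.05. With unmatched 6 h arrays left in place and mirrors left out, their highest other counts were 0, 3, 0, 12, 9, 0 and 27 in the same order.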

How the results depend on the processing

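Keeping the marked spots, the joint fit with slide, the fits within slides and those without the arrays labelled sak1Δ were chosen after the data were seen. Many genes were named because they passed, which favours a high share of kept calls. Over 6033 alternative values of named genes, 5306 kept direction and side of the threshold, 667 kept direction and lost the call, 58 gained one and 2 reversed. For 1268 alternative means of called lists, and of the uncalled cell separation list of sak1Δ against wild type, these numbers were 1058, 197, 6 and 7. Of 560 list medians per harvest 552 stayed within their spread, 6 moved and 2 reversed. Among the other 70 lists without a call, 1792 alternatives gave 125 calls and 99 changes of sign, 5 of them both. Where a value changed, the cause was not tested unless fewer arrays or genes explain it. With the joint fit and slide as a fixed block, 2 genes passed for sak1Δ against wild type, 7 against fkh2Δ and 2 against sep1Δ. Of 45 named genes of sak1Δ against wild type, 2 kept direction and side of the threshold there, 41 lost the call and 2 reversed. Against fkh2Δ 24 of 26 named genes lost the call, and against sep1Δ 19 of 21. The genes that reversed were fip1 (0.82) and fio1 (1.11), and so did the iron uptake list, at 1.40, 1.51 and 1.22. The standard error rose in that fit, and the slide 4 effect it takes out had a mean of -2.09 over the iron uptake list. Cell separation reversed for 12 h against 8 h with slide as a fixed block, alone or in the joint fit (-0.50 in both), and for hydroxyurea within slide 2 (0.15), where only the sep1Δ array had hydroxyurea. The heat shock list of the difference of responses reversed with the brightest probe (-0.018), the cell separation median of sak1Δ at 10 h with the brightest probe (0.065), and that of wild type in hydroxyurea against 8 h with scale normalization (0.089). With slide as a random block, 616 genes passed for sak1Δ. As a fixed block it gave 10 genes for 12 h against 8 h, 18 for hydroxyurea, 778 for temperature and 1 for the difference of responses, and the joint fit gave 10 and 18 for the first 2 of these. Slide as a fixed block could not be fitted for the sak1Δ comparisons or sak1-891 against wild type, nor as a random block for the 3 temperature comparisons, and slide 1 gave no hydroxyurea value. Within slides 1 and 2, 86 and 1331 genes passed for fkh2Δ. For sep1Δ 73 passed within slide 2, and 0 within slide 1, where its single array allows no comparison of stability.

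The scanner log ratio and the series matrix gave 449 and 448 genes for fkh2Δ, 21 and 22 for sep1Δ, 11 and 11 for 12 h against 8 h, 19 and 19 for hydroxyurea, 10 and 11 for sak1-891, and 76 and 79 for temperature. Scale normalization gave 16 for hydroxyurea, 459 for temperature and 3 for the difference of responses, and the brightest probe 12 for sak1-891 and 80 for temperature. Scalings moved the share of higher calls from 89.5% to 100% for 12 h against 8 h (scanner log ratio, matrix, median centring and scale), from 67.3% to 84.2% (scanner log ratio and matrix), 50.6% (median centring) and 93.8% (scale) for hydroxyurea, and from 61.0% to 49.0% (scale) for temperature. No scaling moved the median of all genes by over 0.1. Fitting only the groups compared gave 140 genes for sak1Δ, 477 for sep1Δ, 515 and 406 for sak1Δ against fkh2Δ and sep1Δ, 3 for 12 h against 8 h and 20 for hydroxyurea. Without the hydroxyurea arrays 504 genes passed for sak1Δ, 463 for fkh2Δ and 710 for sak1Δ against sep1Δ, and without the arrays labelled sak1Δ 217 for hydroxyurea. The joint fit without slide gave 41 genes for sak1-891, 857 for temperature and 8 for the difference of responses. With an estimated correlation 4 of 120 list tests passed in place of 49, and the M phase means of -0.41 (sak1Δ, adjusted p = 0.278), 0.52 (fkh2Δ, 0.0520) and -0.28 (sep1Δ, 0.0622) lost their calls. The correlation of the sak1Δ and fkh2Δ differences moved to 0.18 with split wild-type arrays and 0.27 with the marked spots kept.

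The harvest is the replicate block of the germination fit. The fit with no replicate block gave 19 genes for sep1Δ, 0 for 12 h against 8 h and 5 for hydroxyurea. Hours at 36 °C as a replicate block (1 residual degree of freedom for sak1-891) gave 76 genes for sak1-891, with agn1, adg3, myp2, slp1 and plo1 among them, 1170 for temperature and 5 for the difference of responses. The pairing rests on the harvest times of the labels. Same-harvest pairs of arrays correlated by -0.114 to 0.608 in their deviations (18 pairs, median 0.179, 11 over 0.1), against a median of -0.0766 for different harvests. Of the 9 same-harvest pairs without an array labelled sak1Δ, each on one slide, 8 were over 0.1 (median 0.276), but of the 9 with one, on different slides, 3 were (median -0.0434), so the values give the harvest block little support in the sak1Δ comparisons. With each array left out in turn, the counts ranged from 393 to 1042 for sak1Δ, 439 to 803 for fkh2Δ, 18 to 44 for sep1Δ, 781 to 1433 and 446 to 1034 for sak1Δ against fkh2Δ and sep1Δ, 4 to 19 for 12 h against 8 h, 11 to 85 for hydroxyurea, 19 to 66 for sak1-891, 122 to 774 for temperature and 0 to 1 for the difference of responses. The M phase means ranged from -0.45 to -0.36 (sak1Δ), 0.47 to 0.57 (fkh2Δ), -0.31 to -0.21 (sep1Δ) and -0.96 to -0.81 (sak1Δ against fkh2Δ). Without either 26 °C array the temperature comparisons had no value. A lone array left in a group is assumed to vary like the other groups. Signals not well above background and the spots left out, up to 41.6% on slide 4, limit the genes tested with these arrays.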

Other observations

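The values of ura4 and sak1 on single arrays are described here, and no test was run on them. The ura4 transcript was 29.1% to 80.6% of the reference on the 17 germination arrays that measured it. At 8, 10 and 12 h and in hydroxyurea it was 65.5%, 65.1%, 80.6% and 78.1% in wild type. In the same order it was 38.7%, 50.4%, 47.6% and 33.8% in fkh2Δ and 29.1%, 36.3%, 49.8% and 35.3% in sep1Δ. The arrays labelled sak1Δ gave 78.2% at 8 h, 38.1% at 10 h and 49.0% in hydroxyurea, with no value at 12 h. At 6 h it was 47.8% in wild type and 33.6% in fkh2Δ. The sak1 transcript was 50.5% to 106.2% of the reference on the 18 germination arrays, 45.3% to 55.6% in sak1-891, and 69.3% on the 1 of 3 wild-type temperature arrays that measured it.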
